A study of Mus musculus with 9 samples.

How the data were processed

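RNA of brown adipose tissue was measured in 9 male C57Bl/6J mice on a 60% high fat diet, 4 given vehicle and 5 given cotadutide daily for 28 days. The mice were 14 weeks old, were acclimated for 3 weeks and were kept on the diet until about 50 g, without housing at thermoneutrality, per the labels' protocols. RNA came from 30 mg of tissue per mouse. The authors' files hold raw counts of reads per Ensembl gene, 1 file per library, with whole numbers and a different total in each. Polyadenylated RNA was made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and the mouse build mm10. The settings of these tools, the strand setting and the annotation release are not given in the sources used here. Reads of overlapping genes, and of a gene and its antisense partner, could therefore not be told apart. The RNA was isolated after the fat layer of the homogenate had been removed, and polyA selection leaves out most other RNA, so levels refer to polyadenylated RNA only.

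Each deposited file listed 49315 genes, and 49056 of the identifiers were matched to a symbol of the supplied annotation. The 259 without a match took 0.0132% of all counts. Coordinates were those in the files, and transcript length for the bias correction was the file's length column. That length can exceed the length of the mRNA. For Fabp4 it was 4489, the whole span of the gene from 10204088 to 10208576. Groups and mouse numbers came from the labels. Totals per library ranged from 10.8 to 25.1 M counts (M, mega). Filtering with edgeR's filterByExpr left 14747 genes, which held 99.87% of the counts. Counts were scaled by the trimmed mean of M values, with factors from 0.914 to 1.06. The common biological coefficient of variation was 17.0%. Every pair of libraries differed by more than counting noise, since the lowest chi-square per degree of freedom was 12.69, and each library was counted as 1 replicate. Mice were separate animals.

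Genes were tested with edgeR 4.0.16 (glmQLFit with robust dispersion, glmQLFTest) in R 4.3.3, with all 9 libraries, the group as the only term and a Benjamini-Hochberg adjusted p of 0.05. Standard errors (SE) of log2 fold changes were the size of the log2 fold change divided by the square root of the F statistic. The SE of a median over a list came from 1000 resamples of its genes and leaves out the variation between mice. Gene lists were tested with camera of limma 3.58.1, two-sided, on log2 CPM with a prior count of 2, once with the preset inter-gene correlation of 0.01 and once with a correlation estimated per list, and with fry. Adjusted p of lists were over 44 lists. The lists were fixed before the data were examined, as were the main test, the alternatives other than those named as added, and the rule for genes to name. The 44 lists were of thermogenic genes, creatine and calcium cycling, nuclear-encoded complex I, complexes II to V, mitochondrially encoded mRNAs, the citric acid cycle, mitochondrial and peroxisomal fatty acid oxidation, lipogenesis, cholesterol and triglyceride synthesis, lipolysis, lipid uptake, glycolysis, glycogen, branched-chain amino acids, cyclic AMP response, secreted factors, both stress responses, mitochondrial biogenesis, autophagy, insulin signalling, the clock, matrix, cytokines, interferon response, MHC class II, the cell cycle, ribosomal proteins, nuclear-retained RNAs and immediate early genes. The others were markers of macrophages, T and NK cells, B cells, endothelial, mural, fibroblast, skeletal muscle, white adipocyte, shared adipocyte, Schwann and neuronal, erythroid, and mesothelial and lymphatic cells. Some genes were members of more than 1 list, such as Lpl and Fabp4, which counted as lipid uptake genes and as shared adipocyte markers.

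The rule named the focus genes (the drug's receptors, Gipr and core brown fat genes), and the 8 genes with the largest change in each direction among those past the threshold with a mean of at least 5 CPM in a group and no overlap between groups. Gene models without a function-based name, pseudogenes and immunoglobulin segments were left out. From each list described it took the members with the smallest adjusted p, at most 5 for a called list and 3 for others, and for a cell type the 2 most abundant. Only some of these are printed, and a few are not reported here. Scd1 was added after its values were seen. Shares of counts were compared by exact two-sided permutation tests over all splits of 9 libraries into 4 and 5, whose smallest p is 0.00794. Limits for a gene without counts are 3 counts over the group's total, intervals are exact Poisson intervals at 95%, and both cover counting error only.

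The fits were tested on simulated counts with the real means, dispersions and totals of 14747 genes, 5 times with 200 changed genes. At the adjusted p threshold edgeR recovered 1.2% of genes changed by 1.25-fold, 32% at 1.5-fold, 67.6% at 2-fold and 89.2% at 3-fold, and 5.06% of its calls were unchanged genes. Far fewer genes were changed there than the 18.65% called in the real comparison, so these recovery rates do not carry over to it. Camera with the preset correlation called a list shifted by 1.3-fold in all 5 runs, in data whose genes varied independently. It called 0 in 210 tests of unshifted lists, a count that left out the mitochondrial biogenesis list, although that list was not shifted. The alternatives were other scalings, no filter and a stricter one, DESeq2 1.42.0, limma-voom with quality weights, removal of mitochondrial genes, the mouse number as a block, leaving out each mouse, stricter thresholds, and the estimated correlation. Added after the data were examined were fits without vehicle mouse 4 and cotadutide mouse 3, with a muscle score (mean log2 CPM of the muscle markers) as a covariate, with offsets for transcript length and GC content, and with all libraries thinned to the total of the shallowest.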

Results

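Brown adipose tissue is the heat-producing fat depot of mammals, rich in mitochondria and in the uncoupling protein Ucp1. Its polyadenylated RNA was sequenced from male C57Bl/6J mice made obese on a 60% high fat diet. The mice received vehicle or cotadutide, a peptide agonist of the glucagon-like peptide 1 and glucagon receptors, under the skin each day for 28 days. There were 4 vehicle mice and 5 cotadutide mice, with 1 library per mouse. Library totals were 20.8 ± 4.05 M counts (SD, n = 4, range 16.1 to 25.1) for vehicle and 15.9 ± 3.58 M counts (SD, n = 5, range 10.8 to 19.5) for cotadutide. The difference in totals did not pass an exact two-sided permutation test (p = 0.119). The comparison asked which genes of this tissue changed under cotadutide. Values below are CPM, the counts of a gene per 1 M counts of the scaled library total, as mean ± SD with n = 4 for vehicle and n = 5 for cotadutide, and folds are cotadutide against vehicle.

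Cotadutide-treated brown fat carried less leptin mRNA, less skeletal muscle, macrophage and extracellular matrix mRNA, and more mRNA of the respiratory chain and of fatty acid oxidation. The calls of these gene lists were lost with an estimated correlation between genes (camera adjusted p = 0.577 for each). Those of the macrophage and matrix lists were also lost with the muscle mRNA level of each library as a covariate (camera adjusted p = 0.0501 and 0.0602), a fit chosen after the data were examined. Lep, which encodes the adipocyte hormone leptin, was 8.71 times lower (235 ± 125 against 27.1 ± 11.9 CPM, log2 fold change -3.12, SE 0.49, edgeR adjusted p = 0.014). Npr3, the natriuretic peptide clearance receptor, was 4.95 times lower (292 ± 131 against 59.0 ± 9.77 CPM, log2 fold change -2.31, SE 0.32, edgeR adjusted p = 0.0122). Irf4, a transcription factor of thermogenic gene programs, was 8.26-fold higher (13.5 ± 7.0 against 110.4 ± 89.4 CPM, log2 fold change 3.05, SE 0.67, edgeR adjusted p = 0.019). Its 5 cotadutide values spanned 28.3 to 241.7 CPM, all above the highest vehicle value of 22.6 CPM. Cfd, which encodes the secreted protease adipsin, was 3.93-fold higher (443 ± 327 against 1741 ± 308.5 CPM, log2 fold change 1.97, SE 0.41, edgeR adjusted p = 0.0179).

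Other genes with large increases and non-overlapping groups included Acot1 (4.17-fold), Hcar1 (3.02-fold), Aspg (2.85-fold), Pbld2 (2.74-fold) and Slc27a2 (2.56-fold). Acot1 encodes an acyl-CoA thioesterase (edgeR adjusted p = 0.024) and Hcar1 the lactate receptor (edgeR adjusted p = 0.0187). Acot1 and Acot2 are near-identical neighbours, so the split of reads between them was uncertain. The largest decreases with non-overlapping groups, beside Lep and Npr3, included Tph2 (16.1 times lower), a tryptophan hydroxylase of serotonin synthesis, and Prr32 (11.6 times lower). Ankrd1 (14.2 times lower), Myh3 (10.6 times lower), Myh2 (4.72 times lower) and Xirp1 (4.55 times lower) are genes of striated muscle, and the edgeR adjusted p of these 6 genes ranged from 0.0147 to 0.0163. Tph2, Ankrd1, Prr32 and Myh3 each had a mean at or under 7.13 CPM in vehicle mice. The log2 fold change of Acot1 was 3.06 without vehicle mouse 4, that of Cfd 2.59 without vehicle mouse 4, that of Ankrd1 -2.79 without vehicle mouse 1, and that of Prr32 -4.14 without cotadutide mouse 1. In the mm10 coordinates of the files, Irf4 (ENSMUSG00000021356) lay on chromosome 13 from 30749226 to 30766927 and Cfd (ENSMUSG00000061780) on chromosome 10 from 79890853 to 79892656.

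**Figure D1:**
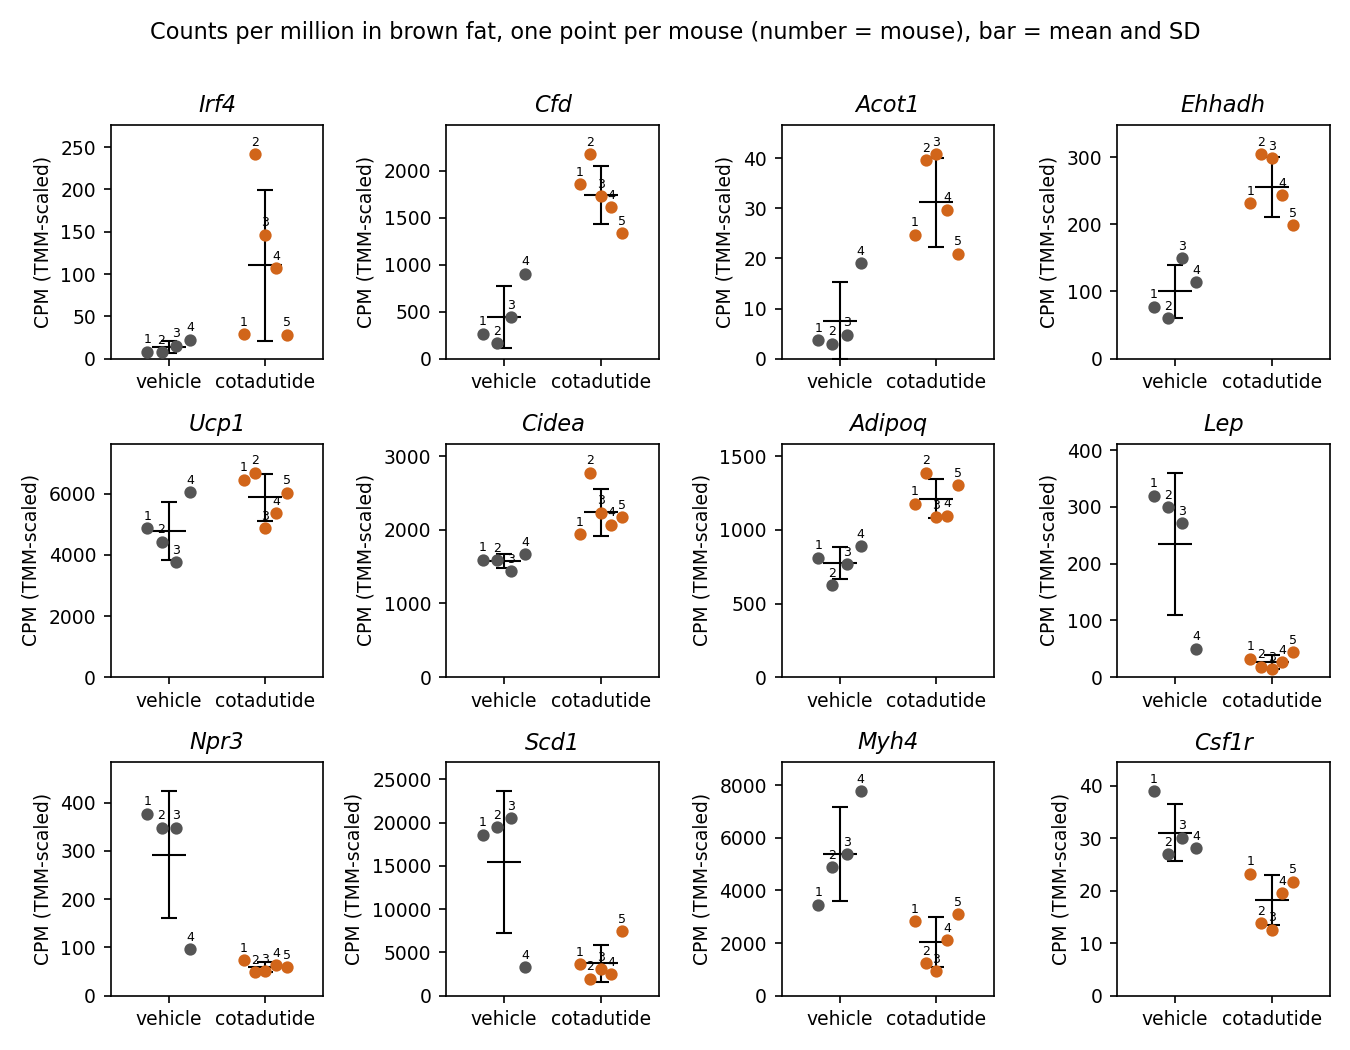
Scaled CPM (linear axis) of 12 genes in brown fat, with 1 point per mouse labelled by its number, 4 vehicle and 5 cotadutide, and bars for the mean and SD. Lep and Npr3 fell from means of 235 and 292 CPM to 27.1 and 59.0 CPM, while vehicle mouse 4 lay at 50.3 CPM for Lep and 3267 CPM for Scd1, far from the other vehicle mice.

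Of 14747 genes tested, 1373 were higher and 1378 lower under cotadutide by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, or 18.65% of the genes tested. A change of at least 2-fold was found for 581 genes, of which 455 fell. The libraries of the groups did not overlap for 903 of the genes that rose and 920 of those that fell. Over all tested genes that share was 15.85%, against 1.59% by chance. The number of calls depended on single libraries. It came to 47 higher and 92 lower without vehicle mouse 1, 42 and 105 without vehicle mouse 2, and 265 and 473 without vehicle mouse 3. It came to 2116 and 1588 without vehicle mouse 4, 465 and 349 without cotadutide mouse 2, and 546 and 818 without cotadutide mouse 3. No gene called in the full comparison was called in the opposite direction in any of these fits. Of the 107 genes named here and below that passed the threshold, 13 still passed it without vehicle mouse 1, 14 without vehicle mouse 2 and 49 without vehicle mouse 3. With the skeletal muscle score of each library as a covariate, edgeR called 0 genes, and 2132 had an unadjusted p under 0.05. That score was higher in every vehicle mouse than in any cotadutide mouse.

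Ucp1 was among the abundant mRNAs of the tissue and did not pass the threshold. It stood at 4781 ± 961 CPM in vehicle and 5886 ± 759 CPM in cotadutide mice (1.23-fold, log2 fold change 0.30, SE 0.14, edgeR adjusted p = 0.159). It passed without vehicle mouse 4 (log2 fold change 0.43, edgeR adjusted p = 0.0312) and by limma-voom (adjusted p = 0.0423). Other core genes of brown fat also missed it by edgeR: Dio2, which activates thyroid hormone (1.25-fold, adjusted p = 0.575), Ppargc1a (1.32-fold, adjusted p = 0.176), Adrb3 (1.21-fold, adjusted p = 0.254), Elovl3 (1.42-fold, adjusted p = 0.433) and Gk (1.12-fold, adjusted p = 0.486). Elovl3 rested on vehicle mouse 4, at 199 CPM against 29.1 to 74.3 CPM in the other vehicle mice. Without it Elovl3 passed at a log2 fold change of 1.27 (edgeR adjusted p = 0.0182), and it also passed by limma-voom (adjusted p = 0.0319). Ppargc1a passed without cotadutide mouse 1 (log2 fold change 0.51, edgeR adjusted p = 0.0356), and Gk without both vehicle mouse 4 and cotadutide mouse 3 (edgeR adjusted p = 0.0317). Cidea, a lipid droplet protein of brown adipocytes, rose 1.43-fold (1571 ± 94.9 against 2238 ± 319 CPM, edgeR adjusted p = 0.0184). Pck1, which supplies glycerol phosphate in fat cells, rose by 0.59 on the log2 scale (2610 ± 458 against 3925 ± 572.5 CPM, edgeR adjusted p = 0.0232). Of the drug's receptors, Glp1r had 0 counts in all 9 libraries, which allows up to 0.036 CPM over the vehicle group and 0.0377 CPM over the cotadutide group from counting error. Gcgr had 7 counts over the 4 vehicle libraries and 17 over the 5 cotadutide libraries, too few to enter the test. These are 0.084 CPM (exact 95% interval 0.0338 to 0.173) and 0.214 CPM (0.124 to 0.342). The related receptor Gipr stood at 3.34 ± 0.28 CPM and 4.36 ± 0.772 CPM (edgeR adjusted p = 0.115, but 0.0489 by limma-voom). Fgf21, a hormone that brown fat can release, had 57 and 27 counts over the groups and was not tested.

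Of the 44 gene lists fixed before the data were examined, camera with its preset correlation called 12 higher and 7 lower, and 25 were not called. None was called with an estimated correlation, where the adjusted p of the 19 lists ranged from 0.577 to 0.595. The estimated correlation reached 0.788 for complex I and 0.913 for ribosomal proteins, against the preset 0.01. Of 100 splits of the 9 libraries, 21, the real one among them, gave as many called lists with the preset correlation. Chance is therefore not excluded for the number of lists. The rotation test fry, which asks if a list moves one way without comparing it with other genes, gave an adjusted p under 0.05 for 10 lists, all among the 19. The skeletal muscle and macrophage lists (fry adjusted p = 0.0611 for each) and complexes II to V (0.0501) missed it. So did creatine cycling and mitochondrial biogenesis (fry adjusted p = 0.052 for each) and mitochondrially encoded mRNAs (0.0874). The inflammatory (fry adjusted p = 0.0938), ribosomal protein (0.0939) and immediate early lists (0.132) missed it too.

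**Figure D2:**
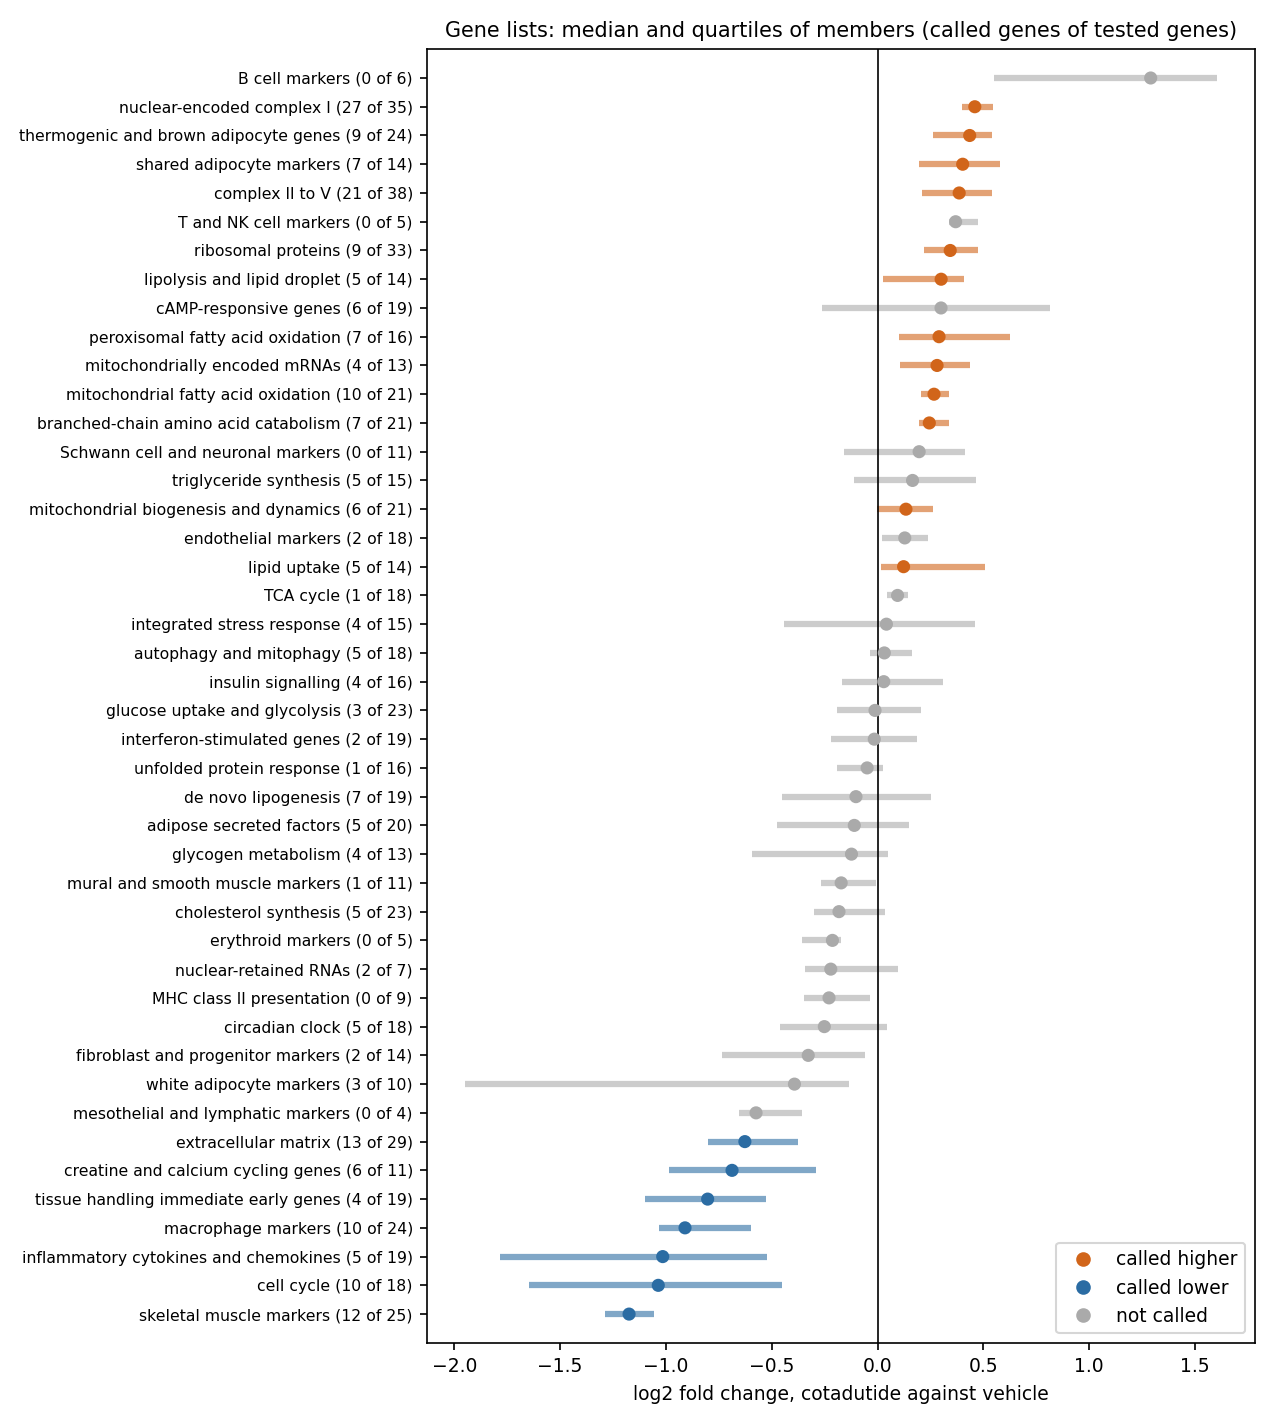
Median (point) and quartiles (bar) of the log2 fold changes of the members of each of the 44 gene lists, with the number of called genes among those tested in parentheses. Colour marks lists called higher or lower by camera with the preset correlation. The medians of called lists ran from -1.17 for skeletal muscle markers to 0.46 for nuclear-encoded complex I.

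Genes of the mitochondrial respiratory chain rose together. Of the nuclear-encoded subunits of complex I, the NADH dehydrogenase, 27 of 35 rose and 0 fell, or 32 when adjusted over the list alone, with a median of 1.38-fold (camera adjusted p = 7e-11; adjusted p = 0.577 with an estimated correlation). With the muscle score as a covariate its median log2 fold change was 0.39, against 0.46 without. They included Ndufa1 (1.65-fold, edgeR adjusted p = 0.0171), Ndufa6 (1.46-fold) and Ndufs7 (1.45-fold). Of complexes II to V, 21 of 38 rose and 0 fell, or 27 higher and 1 lower when adjusted over the list alone, with a median of 1.31-fold (camera adjusted p = 5.4e-09; adjusted p = 0.577 with an estimated correlation). The cytochrome c oxidase subunits Cox6a1 (1178 ± 120 against 1935 ± 338 CPM, 1.64-fold, edgeR adjusted p = 0.0147), Cox4i1 (1.58-fold) and Cox8a (1.44-fold) were among them. Of the mRNAs encoded in the mitochondrial genome, 4 of 13 rose and 0 fell, or 6 when adjusted over the list alone (median 1.22-fold, camera adjusted p = 0.00727; adjusted p = 0.595 with an estimated correlation). These included mt-Nd3 (1.39-fold, edgeR adjusted p = 0.0461) and mt-Co3 (1.40-fold, edgeR adjusted p = 0.0231). All 4 were among the low members of the list, with means of 26.0 to 147 CPM in vehicle mice, although mitochondrially encoded genes together took 18.6% of the counts, so their folds are uncertain. None of the 7 members at or above 5100 CPM passed by edgeR, with changes from 1.09 times lower to 1.23-fold higher (adjusted p from 0.0711 to 0.939). That list lost its call after a correction for transcript length and GC content chosen after the data were examined (camera adjusted p = 0.143). Its median log2 fold change was then 0.19, against 0.28 without the correction. Of the mitochondrial biogenesis and dynamics list, 5 of 21 rose and 1 fell, both over all genes and when adjusted over the list alone (median 1.10-fold, camera adjusted p = 0.0363; adjusted p = 0.595 with an estimated correlation). Phb2, Tomm40 and Esrra rose, and Mfn1, which fuses mitochondria, fell 1.19 times. Its call was lost without vehicle mouse 2 or 3, or cotadutide mouse 2, 4 or 5 (camera adjusted p = 0.0636, 0.0656, 0.0529, 0.0714 and 0.0654). It was also lost with a stricter filter and without mitochondrial genes (camera adjusted p = 0.0533 and 0.0517). The list of the citric acid cycle was not called, with 1 of 18 higher (median 1.07-fold, camera adjusted p = 0.123), although it was called without vehicle mouse 1 (camera adjusted p = 0.026). Cytosolic ribosomal protein genes also rose, with 9 of 33 higher and 0 lower, or 11 when adjusted over the list alone (median 1.27-fold, camera adjusted p = 1.93e-07; adjusted p = 0.595 with an estimated correlation). Rplp2 (1.65-fold) and Rpl3 (1.37-fold) were examples, and many such genes have processed copies that share reads. In a wider scan by symbol, chosen after the data were examined, 8 of 50 Rpl genes were higher and 0 lower and 8 of 43 Rps genes were higher and 2 lower by edgeR. The excess of higher genes over the other named protein-coding genes tested did not pass in either family (Fisher's exact adjusted p = 0.814 and 0.572).

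Genes that bind, release and burn lipid rose as well. Of the mitochondrial fatty acid oxidation list, 10 of 21 rose and 0 fell, or 15 higher and 1 lower when adjusted over the list alone, with a median of 1.20-fold (camera adjusted p = 2.84e-06; adjusted p = 0.577 with an estimated correlation). Etfb (1.70-fold, edgeR adjusted p = 0.0178), Eci1 (1.69-fold), Acot2 (1.63-fold) and the long-chain dehydrogenase Acadl (1.28-fold) were among them. Of the peroxisomal list, 7 of 16 rose and 0 fell, or 9 when adjusted over the list alone (median 1.22-fold, camera adjusted p = 0.000337; adjusted p = 0.577 with an estimated correlation). Ehhadh, the peroxisomal bifunctional enzyme, rose 2.55-fold (100.3 ± 39.7 against 255 ± 45.05 CPM, edgeR adjusted p = 0.0148). Acaa1a (1.44-fold) and Pex11a (1.25-fold) rose too, the former with a close paralog. Of the lipolysis and lipid droplet list, 5 of 14 rose and 0 fell, or 8 higher and 1 lower when adjusted over the list alone (median 1.23-fold, camera adjusted p = 0.0104; adjusted p = 0.577 with an estimated correlation). They were led by Bscl2, Pnpla2, which encodes the triglyceride lipase ATGL (1.40-fold, edgeR adjusted p = 0.0165), its activator Abhd5 (1.59-fold) and Mgll (1.33-fold). Of the lipid uptake list, 4 of 14 rose and 1 fell, or 5 and 1 when adjusted over the list alone (median 1.09-fold, camera adjusted p = 0.038; adjusted p = 0.577 with an estimated correlation). The fatty acid transporter Slc27a1 (1.80-fold, edgeR adjusted p = 0.0133), the fatty acid binding protein Fabp4 (1.35-fold) and lipoprotein lipase Lpl (1.44-fold) rose. Its call was lost without vehicle mouse 2 or cotadutide mouse 2, 4 or 5 (camera adjusted p = 0.0599, 0.0529, 0.0566 and 0.058). Of the branched-chain amino acid catabolism list, 7 of 21 rose and 0 fell, or 12 when adjusted over the list alone (median 1.19-fold, camera adjusted p = 1.01e-05; adjusted p = 0.577 with an estimated correlation). The transaminase Bcat2 (1.88-fold, edgeR adjusted p = 0.0145), Hsd17b10 (1.74-fold) and Dbt (1.49-fold) were among them.

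Of the thermogenic and brown adipocyte list, 9 of 24 rose and 0 fell, and 9 rose when adjusted over the list alone (median 1.35-fold, camera adjusted p = 1.77e-05; adjusted p = 0.577 with an estimated correlation). Besides Irf4 and Cidea these included Clstn3 (1.75-fold, edgeR adjusted p = 0.014), the potassium channel Kcnk3 (2.25-fold) and Pank1 (1.43-fold). Of the markers shared by brown and white adipocytes, 7 of 14 rose and 0 fell, or 10 when adjusted over the list alone (median 1.32-fold, camera adjusted p = 1.34e-05; adjusted p = 0.577 with an estimated correlation). Adiponectin, encoded by Adipoq, rose 1.57-fold (774 ± 109.6 against 1211 ± 132.5 CPM, edgeR adjusted p = 0.0147), Retsat 1.51-fold and the adipogenic factor Cebpa 1.33-fold. Markers of white adipocytes were not called as a list (median 1.31 times lower, camera adjusted p = 0.0694), and 3 of 10 fell, also when adjusted over the list alone. Those were Lep, Npr3 and Mest, which was 5.50 times lower. The list was called lower without vehicle mouse 4 or cotadutide mouse 1 (camera adjusted p = 0.016 and 0.0402). The de novo lipogenesis list was not called (camera adjusted p = 0.885), with 4 of 19 higher and 3 lower, or 5 and 4 when adjusted over the list alone. Acacb (1.60-fold), Elovl5 (1.48-fold) and Thrsp (1.45-fold) rose. Scd1, the stearoyl-CoA desaturase, was 4.14 times lower (15470 ± 8174 against 3734 ± 2176 CPM, edgeR adjusted p = 0.025) and was singled out after its values were seen. Of the triglyceride synthesis list, 5 of 15 rose and 0 fell, or 5 and 1 when adjusted over the list alone, and it was not called (camera adjusted p = 0.0694). Dgat1 (1.49-fold), Gpat4 (1.98-fold) and Mogat1 (1.48-fold) rose. That list was called higher without vehicle mouse 1 or 4, or cotadutide mouse 1 or 3 (camera adjusted p = 0.046, 0.042, 0.0402 and 0.0201), and with no filter, a stricter filter or limma-voom (camera adjusted p = 0.031, 0.041 and 0.0379).

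Macrophage and matrix genes fell. Of the macrophage markers, 10 of 24 fell and 0 rose, or 18 when adjusted over the list alone, with a median 1.88 times lower (camera adjusted p = 2.05e-07; adjusted p = 0.577 with an estimated correlation). The chemokine receptor Ccr2 (2.15 times lower, edgeR adjusted p = 0.018), the integrin Itgax (2.46 times lower), Csf1r (31.0 ± 5.44 against 18.2 ± 4.74 CPM, 1.71 times lower) and the abundant lysozyme gene Lyz2 (1.61 times lower) were among them. Of the extracellular matrix list, 13 of 29 fell and 0 rose, or 19 when adjusted over the list alone (median 1.54 times lower, camera adjusted p = 2.29e-07; adjusted p = 0.577 with an estimated correlation). Ccn2, a matrix-associated growth factor, had the smallest adjusted p of all genes (2.40 times lower, edgeR adjusted p = 0.00685), and the collagen crosslinking enzyme Lox (2.77 times lower), Bgn and Col5a3 also fell. Of the inflammatory cytokines and chemokines, 4 of 19 fell and 1 rose, or 7 and 1 when adjusted over the list alone (median 2.02 times lower, camera adjusted p = 0.00265; adjusted p = 0.577 with an estimated correlation). Cxcl1 (4.12 times lower, edgeR adjusted p = 0.0343), Ccl2 (3.72 times lower) and Nos2 (1.95 times lower) fell, and Il1rn, the interleukin 1 receptor antagonist, rose 2.05-fold. Without cotadutide mouse 1 the log2 fold change was -2.74 for Cxcl1 and -2.63 for Ccl2. Of the cell cycle list, 9 of 18 fell and 1 rose, or 11 and 1 when adjusted over the list alone (median 2.05 times lower, camera adjusted p = 6.41e-06; adjusted p = 0.577 with an estimated correlation). Birc5 (4.02 times lower), Top2a (3.52 times lower) and Tpx2 (2.71 times lower) fell from vehicle levels of 1.28 to 3.81 CPM, and Mcm7 rose 1.36-fold. Of the immediate early genes, which tissue handling can induce, 4 of 19 fell and 0 rose, also when adjusted over the list alone (median 1.74 times lower, camera adjusted p = 0.000845; adjusted p = 0.595 with an estimated correlation). They were Klf6, Dusp1, Jun and Ccn1. The macrophage and matrix medians fell in size to log2 -0.31 and -0.30 with the muscle score as a covariate, where neither was called (camera adjusted p = 0.0501 and 0.0602).

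Skeletal muscle mRNA was lower in the cotadutide libraries. Of 25 muscle markers 12 fell and 0 rose, or 21 when adjusted over the list alone, with a median 2.26 times lower (camera adjusted p = 1.84e-08; adjusted p = 0.577 with an estimated correlation). The most abundant were Myh4, a fast myosin heavy chain (5374 ± 1792 against 2039 ± 950 CPM, edgeR adjusted p = 0.0254), and Acta1, skeletal actin (4710 ± 1712 against 1980 ± 992 CPM, edgeR adjusted p = 0.0465). Casq1 (2.89 times lower) and Mb, myoglobin (2.70 times lower), fell with them. Reads of Myh2 and Myh4 could be divided with neighbouring myosin genes of near-identical sequence. Together the 25 markers took 3.60% ± 1.14 (SD, n = 4) of the counts in vehicle and 1.49% ± 0.72 (SD, n = 5) in cotadutide libraries. By an exact two-sided permutation test added after the data were examined, p was 0.00794, the smallest that 4 against 5 libraries allow (adjusted p = 0.0397 over 5 measures). Of the creatine and calcium cycling list, 5 of 11 fell and 1 rose, or 6 and 2 when adjusted over the list alone (median 1.61 times lower, camera adjusted p = 0.038; adjusted p = 0.577 with an estimated correlation). Ckmt2 (2.77 times lower), a mitochondrial creatine kinase of striated muscle, the creatine transporter Slc6a8 (1.61 times lower) and Gamt (1.74 times lower) fell. Ckb, the brain-type creatine kinase, rose 2.48-fold (51.9 ± 24.9 against 128.7 ± 38.8 CPM, edgeR adjusted p = 0.0223). The list lost its call without vehicle mouse 4 or cotadutide mouse 2, 3, 4 or 5 (camera adjusted p = 0.168, 0.0549, 0.0593, 0.0714 and 0.058). It was also lost with a stricter filter, with limma-voom and without mitochondrial genes (camera adjusted p = 0.0535, 0.0903 and 0.0579). With the muscle score as a covariate its median log2 fold change turned from -0.69 to 0.0318 (camera adjusted p = 0.638).

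Markers of other cell types were not called. Endothelial markers had a median of 1.09-fold (camera adjusted p = 0.191) and Sox18 and Emcn rose, 2 of 18 over all genes and 1 when adjusted over the list alone. The list was called higher without vehicle mouse 2 (camera adjusted p = 0.0392). Fibroblast and progenitor markers had 1 of 14 higher and 1 lower (Fbn1, 1.73 times lower), or 0 and 1 when adjusted over the list alone, with a camera adjusted p of 0.157. That list was called lower without vehicle mouse 2 or cotadutide mouse 1 (camera adjusted p = 0.0179 and 0.0402). Mural and smooth muscle markers had 1 of 11 higher, or 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.424). Their member Des, which striated muscle also expresses, stood at 810 ± 249.8 and 443.8 ± 160.6 CPM (edgeR adjusted p = 0.0524), and passed without cotadutide mouse 1 or 5 (edgeR adjusted p = 0.0319 and 0.0423). It also passed with upper quartile scaling, a stricter filter or no mitochondrial genes (edgeR adjusted p = 0.0465, 0.0388 and 0.047) and with DESeq2 (adjusted p = 0.0123). No member of 5 cell type lists was called, over all genes or when adjusted over the list alone. They were B cells (6 tested, camera adjusted p = 0.824), T and NK cells (5 tested, 0.822), Schwann cells and neurons (11 tested, 0.575), erythroid cells (5 tested, 0.295), and mesothelial and lymphatic cells (4 tested, 0.261). B cell genes stood apart in cotadutide mouse 3, with 8.25 CPM of Cd79b and 5.83 CPM of Cd22, against at most 1.15 and 0.771 CPM in the other cotadutide mice. The T and NK cell list was also highest in that mouse, with a mean log2 deviation of 2.08 against at most 0.247 in any other library. Without that mouse the median of the B cell list turned from log2 1.29 to -0.40 and that of the T and NK cell list from 0.37 to -0.39. The most abundant B cell gene, Ighm, did not pass the threshold (77.3 ± 31.6 against 33.1 ± 19.95 CPM, edgeR adjusted p = 0.0707), but did so without cotadutide mouse 3 (edgeR adjusted p = 0.0441), without both that mouse and vehicle mouse 4 (edgeR adjusted p = 0.0211), and by limma-voom (adjusted p = 0.0135).

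**Figure D3:**
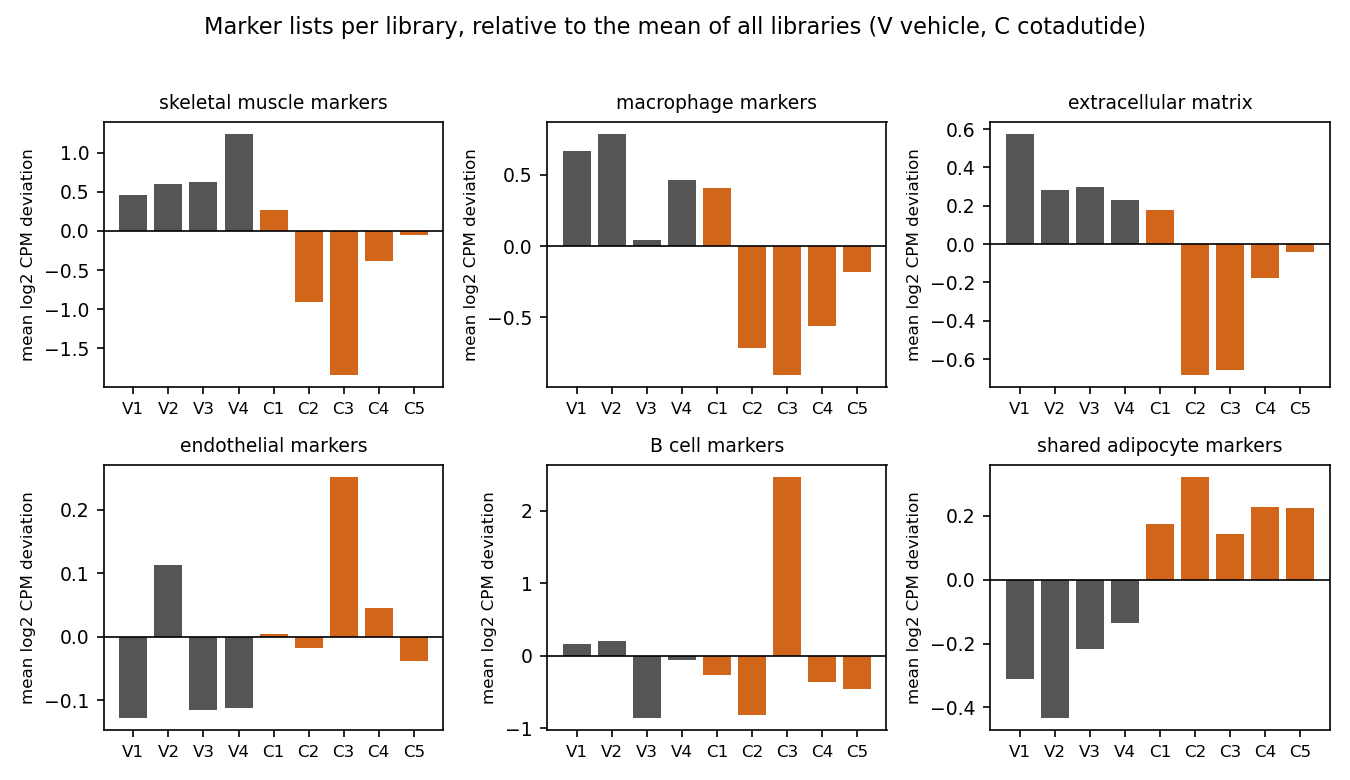
Mean log2 CPM of the members of 6 marker lists in each library, as the deviation from the mean of all 9 libraries (V1 to V4 vehicle, C1 to C5 cotadutide). Muscle markers lay at 0.458 to 1.24 in vehicle and -1.84 to 0.267 in cotadutide mice, and B cell markers at 2.47 in cotadutide mouse 3.

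The remaining lists were not called, and their named members moved in both directions. Of the genes that respond to cyclic AMP, 4 of 19 rose and 2 fell, or 6 and 4 when adjusted over the list alone (camera adjusted p = 0.219). Rgs2 rose 2.53-fold (edgeR adjusted p = 0.014) and Pde4d 1.72-fold, and Dusp1 fell 1.66 times. Of the circadian clock list, 1 of 18 rose and 4 fell, or 1 and 6 when adjusted over the list alone, with Nr1d2 1.37 times lower (camera adjusted p = 0.123). Of the autophagy list, 4 of 18 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.293). Atg7 rose 1.85-fold and Gabarapl1 1.45-fold, and the cargo receptor gene Sqstm1 fell 1.39 times. Of the integrated stress response list, 2 of 15 rose (Asns and Pck2) and 2 fell, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.824). Its transcription factor Atf4 fell 1.35 times (edgeR adjusted p = 0.0156). Of the insulin signalling list, 3 of 16 rose and 1 fell, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.847). Irs2 rose 1.80-fold and Grb14, an inhibitor of the insulin receptor, fell 1.70 times. Of the glycolysis list, 2 of 23 rose, among them Ldhb, and 1 fell (Pfkm, the muscle phosphofructokinase, 2.02 times lower), also when adjusted over the list alone (camera adjusted p = 0.865). Of the glycogen list, 4 of 13 fell and 0 rose by edgeR, and 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.205). Of the interferon-stimulated list, 2 of 19 rose, also when adjusted over the list alone, with Ifi27l2a 2.18-fold higher (camera adjusted p = 0.865). Cholesterol synthesis had 2 of 23 higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 0.205). Adipose secreted factors had 2 of 20 higher and 3 lower, or 2 and 5 when adjusted over the list alone (camera adjusted p = 0.574). The unfolded protein response had 1 of 16 lower, or 0 when adjusted over the list alone (camera adjusted p = 0.424). MHC class II presentation had 0 of 9 called by edgeR either way, also when adjusted over the list alone (camera adjusted p = 0.191). Nuclear-retained RNAs had 2 of 7 lower, also when adjusted over the list alone (camera adjusted p = 0.459). Signs differed between measures for some uncalled lists. Camera's direction was up for de novo lipogenesis (median log2 fold change -0.10, mean -0.19) and for glycolysis (median -0.01, mean -0.01). It was up for the interferon list (median -0.02, mean 0.01) and for the integrated stress response (median 0.04, mean -0.10), and down for MHC class II (median -0.23, mean 0.06).

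Mitochondrially encoded genes took 18.6% ± 1.18 (SD, n = 4) of the counts in vehicle and 20.1% ± 1.16 (SD, n = 5) in cotadutide libraries (exact two-sided permutation p = 0.119, adjusted p = 0.149). Ucp1 took 0.488% ± 0.0786 and 0.574% ± 0.0609 of the counts (exact two-sided permutation p = 0.111, adjusted p = 0.149). The 10 most abundant genes of each library took 22.1% ± 0.97 and 22.7% ± 1.03 (exact two-sided permutation p = 0.437). The leading principal component of the 500 most variable genes held 61.9% of their variance and separated the groups, with vehicle mice from -20.9 to -13.1 and cotadutide mice from -1.56 to 34.2. Among cotadutide mice it ran in the reverse order of the muscle score, from mouse 1 (score 0.267) to mouse 3 (score -1.84). Among vehicle mice it ran in the same order as that score, from mouse 1 (0.458) to mouse 4 (1.24). Group and muscle mRNA were therefore not separated on this component. Vehicle mouse 4 stood apart on the next component, which held 14.2%, at -16.5 against 6.79 to 8.71 in the other vehicle mice. Without vehicle mouse 4 and cotadutide mouse 3, a choice made after the data were examined, 1887 genes were higher and 1419 lower.

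**Figure D4:**
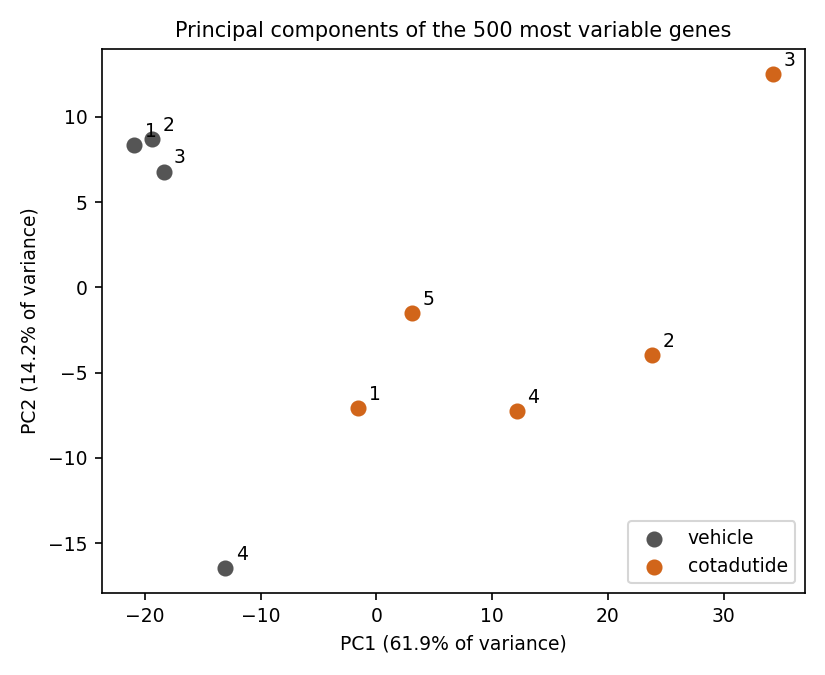
Principal components of the 500 most variable genes (log2 CPM), with 1 point per library labelled by mouse number and coloured by group. PC1 (61.9% of the variance) runs from -20.9 in vehicle mouse 1 to 34.2 in cotadutide mouse 3, and PC2 (14.2%) sets vehicle mouse 4 apart at -16.5.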

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

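Among the tests below, the comparison of endothelial with macrophage markers, the muscle covariate test of OXPHOS mRNAs and both counts of genes under exchanged labels were chosen after the result was seen, as were the fits with a muscle covariate, with length and GC offsets and with thinned libraries. A library was picked out where its gap to the nearest of its group took an unusually large part of the group's range. This was examined in 334 groups of values, of which about 16.7 would be picked out by chance at 1 in 20, and 24 were, 9 of them in vehicle mouse 4. These groups are not independent, since genes of a library move together. The SE of medians below are over member genes and leave out the variation between mice. Where such an SE is used to argue against an explanation, the argument was not tested over mice.

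Vehicle mouse 4 lay far below the other vehicle mice in Lep (50.3 against 271 to 320 CPM), Npr3 (96.5 against 348 to 377 CPM) and Scd1 (3267 against 18620 to 20540 CPM). It lay above them in Kcnk3 (324 against 162 to 179 CPM), Ppargc1a (29.9 against 20.03 to 20.88 CPM) and Eci1 (725 against 513 to 534 CPM). The same was seen for mt-Nd3 (200.2 against 126.4 to 133.7 CPM), the lipid uptake list (mean log2 deviation -0.0259 against -0.149 to -0.145) and skeletal actin Acta1 (7262 against 3592 to 4021 CPM).

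A wrong group label is a possible explanation for vehicle mouse 4. On an axis from the other vehicle mice (0) to the cotadutide mice (1) it lay at 0.584, above cotadutide mouse 1, placed in the same way at 0.496. With vehicle mouse 4 counted as a cotadutide mouse 2840 genes were called by edgeR, against 2751 with the labels as given, so a single wrong label stays open. Leaving this mouse out gave 3704 genes, more than with either label. Its muscle score of 1.24 and its place on the leading principal component (-13.1 against -1.56 or more) lay on the vehicle side of every cotadutide mouse. That component followed muscle mRNA among cotadutide mice, so the place may not be separate evidence from the score. The mean of vehicle mouse 4 lay on the vehicle side in 12 of the 19 called lists, among them macrophage (0.466) and shared adipocyte genes (-0.134). Complex I (-0.0114 against -0.0026 or more) and thermogenic genes (0.0379 against 0.0463 or more) did so narrowly. In 7 lists it lay among the cotadutide mice, such as ribosomal proteins (0.134 against -0.0461 to 0.449), lipolysis (0.0778 against -0.119 to 0.185) and the inflammatory list (-0.331 against -0.94 to 0.35). The lists were called with this mouse counted as vehicle, which favours its vehicle side, so their count cannot decide its label. An exchange with a cotadutide mouse was not settled. Cotadutide mouse 1 did lie under 0.5, as predicted for an exchange. Exchanging vehicle mouse 4 with any of the 5 cotadutide mice left at most 101 genes, which goes against it. But that count was chosen after the result was seen, and such counts fell easily. With the labels as given, 139 genes were called without vehicle mouse 1 and 147 without vehicle mouse 2. A vehicle mouse that differed for biological reasons was not tested.

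Muscle, macrophage and matrix mRNAs were lower together under cotadutide. A smaller share of all non-adipocyte cells is argued against, since the median of endothelial markers lay 1.04 above that of macrophage markers in log2 fold change (SE 0.0972). The muscle markers varied together between mice of a group (median pairwise correlation 0.886), as one common amount of muscle RNA would give, whether from dissection or from the tissue. Whether muscle tissue also brought the macrophage and matrix mRNAs cannot be told apart from the treatment: with the muscle score as a covariate their median moved from -0.70 to -0.30 (SE 0.0548), but the score itself differed between the groups (correlation with group -0.744). An effect of cotadutide on macrophages and matrix stays open.

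OXPHOS mRNAs, the 73 nuclear-encoded genes of complexes I to V, were higher under cotadutide. Bias from the length in the files and from GC content, as the whole cause, is argued against. The median log2 fold change was 0.34 (SE 0.0232) after offsets for them, against 0.45 before. The offsets were fitted to the length trend over all genes, so its fall (Spearman rho -0.227 before and -0.0171 after) was built in. The length in the files can exceed that of the mRNA, so a bias from mRNA length stays open. For ribosomal protein genes the median was 0.26 (SE 0.045) after the offsets, against 0.34 before. After thinning the median was 0.43, but thinning keeps the expected CPM of abundant genes, so it could not decide if the lower depth was a cause. With the muscle score as a covariate the median was 0.38 (SE 0.021), which goes against a smaller share of skeletal muscle RNA as the whole cause. That fit called 0 genes by edgeR, and the score differed between the groups (correlation with group -0.744), so muscle and treatment were not fully separated. The move of the muscle markers from -1.17 to 0.042 in that fit was built in, since the score is their mean. A smaller share of other cells and a change within adipocytes stay open.

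Cotadutide mouse 3 was high in Cd79b (8.25 against 0.566 to 1.15 CPM), Cd22 (5.83 against 0.321 to 0.771 CPM), the B cell list (2.47 against -0.824 to -0.261) and the endothelial list (0.252 against -0.0388 to 0.0445). Its T and NK cell list was also the highest of the cotadutide mice (2.08 against -1.07 to 0.0431), although it was not picked out. Cotadutide mouse 2 was high in Mgll (2028 against 1589 to 1687 CPM) and Fabp4 (15590 against 12840 to 13090 CPM), and low in Dusp1 (80.9 against 109.8 to 115 CPM) and Elovl5 (57.5 against 71.0 to 77.3 CPM). Cotadutide mouse 5 was low in Acot2 (123.9 against 144.6 to 149.9 CPM), Slc27a1 (364 against 439 to 461 CPM) and Mcm7 (20.9 against 22.3 to 22.9 CPM), and high in mural markers (0.104 against -0.116 to -0.0644). Cotadutide mouse 1 was high in the unfolded protein response (0.0856 against -0.0883 to -0.045), vehicle mouse 1 in T and NK cell markers (0.247 against -0.287 to -0.217) and vehicle mouse 2 in endothelial markers (0.113 against -0.128 to -0.113).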

How the results depend on the processing

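The fits without vehicle mouse 4 and cotadutide mouse 3, with the muscle covariate, with length and GC offsets and with thinned libraries were chosen after the data were examined. Against 1373 genes higher and 1378 lower, other scalings, a stricter filter, DESeq2, removal of mitochondrial genes, the offsets and thinning gave 1064 to 1674 higher and 1203 to 1718 lower, within 1.5 times. Without a filter 900 genes were higher, over 28583 genes tested, and with limma-voom 2210. An adjusted p under 0.01 left 3 higher and 3 lower, and an absolute log2 fold change of at least 1 left 581 of 2751 genes, 455 of them lower. Leaving out 1 mouse gave 42 (without vehicle mouse 2) to 2116 (without vehicle mouse 4) higher and 92 (without vehicle mouse 1) to 1724 (without cotadutide mouse 1) lower, with fewer samples in each fit. With the muscle score edgeR called 0 higher and 0 lower (2132 at an unadjusted p under 0.05, smallest adjusted p 0.13), and the median SE rose from 0.14 to 0.2. In none of these fits was a called gene called in the opposite direction. An estimated correlation left 0 lists higher and 0 lower, against 10 to 14 and 6 to 10 under the other alternatives. Of 100 splits of the 9 libraries, 1, the real one, gave as many genes. The highest other gave 1428 by parting cotadutide mice 2 to 5 from the rest. A share of 1 in 100 is the smallest these splits can show, so chance is argued against for the number of genes but not excluded. For the 19 called lists 21 of the 100 splits gave as many, with 25 at most, so chance is not excluded for the number of lists.

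The mouse numbers do not pair the mice: same-numbered mice correlated at 0.135, -0.04, 0.0229 and -0.0107, and 2 libraries were closest to their own number. With the number as a block 516 genes were higher and 768 lower, and the interferon list's median turned to 0.0823. The lipid uptake and mitochondrial biogenesis lists lost their calls (camera adjusted p = 0.0699 and 0.0628), and the white adipocyte and fibroblast lists passed as lower (camera adjusted p = 0.0324 and 0.0342), as did Des (edgeR adjusted p = 0.0401).

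Of the results that turned in direction, the muscle and creatine lists and Acta1 had been called, and turned under the muscle covariate, which is built from the muscle markers. The B cell list, not called before, passed as lower in that fit (camera adjusted p = 0.0115). For the rest the cause was not tested. Without a filter the medians were -0.0494 (integrated stress response), -0.0142 (autophagy), -0.0153 (insulin signalling) and 0.429 (mesothelial). With limma-voom they were -0.0591 (insulin signalling) and -0.154 (T and NK cells). With the offsets they were 0.0203 (lipogenesis), 0.0185 (glycolysis) and -0.00988 (integrated stress response). Without vehicle mouse 4 and cotadutide mouse 3, Cd79b was at -0.00213, glycolysis at 0.0404, T and NK cells at -0.66, B cells at -0.28 and nuclear-retained RNAs at 0.10. With the muscle covariate, Acta1 was at 0.0586, Cd79b at -1.57, Cd22 at -0.80, Des at 0.0611, creatine at 0.0318, lipogenesis at 0.0104, glycolysis at 0.11, glycogen at 0.19, the unfolded protein response at 0.0523, T and NK cells at -1.24, B cells at -1.53, endothelial at -0.0539, muscle at 0.042, white adipocyte at 0.13 and nuclear-retained RNAs at 0.0466. Leaving out 1 mouse gave Dio2 from -0.0266 to 0.52, glycolysis -0.0709 to 0.0357, integrated stress response -0.0415 to 0.12, interferon -0.105 to 0.088, Schwann -0.0724 to 0.44, nuclear-retained -0.33 to 0.0504, insulin -0.0935 to 0.0299, T and NK cells -0.39 to 0.56, B cells -0.40 to 1.51 and autophagy -0.00662 to 0.0416. Lists called in an added fit alone were MHC class II and erythroid, lower with the muscle covariate (camera adjusted p = 0.0115 and 0.012) and with the offsets (0.041 for each), Schwann, higher with the covariate (0.0247), and the circadian clock and MHC class II, lower with thinning (0.0481 for each). Depth limits the low genes: Gcgr and Fgf21 were tested only without a filter (edgeR adjusted p = 0.285 and 0.233).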

Other observations

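The scan of gene families reported here was chosen after the data were examined, and its genes are not independent. Genes were grouped by the stem of their symbol into 164 families of at least 10 tested protein-coding genes. The calls in each were compared with those of the other tested protein-coding genes with a function-based name. The test was Fisher's exact test, two-sided, adjusted over both directions. Genes of the mitochondrial ribosome rose: 19 of 49 Mrpl genes of its large subunit (median 1.26-fold, adjusted p = 3.58e-06) and 11 of 29 Mrps genes of its small subunit (median 1.25-fold, adjusted p = 0.00165), with 0 lower in either by edgeR. Of 14 Timm genes, which serve import through the inner mitochondrial membrane, 7 rose and 0 fell by edgeR (median 1.23-fold, adjusted p = 0.00495). Of 32 collagen genes, 17 fell and 1 rose (median 1.52 times lower, adjusted p = 5.12e-07). The medians of these 4 families kept their direction under both other scalings, without mitochondrial genes and with length and GC offsets.

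Zinc finger genes with the stem Zfp were called less often than other genes in both directions, with 11 of 333 higher and 9 lower (Fisher's exact adjusted p = 0.000797 and 1.22e-05). Of 42 genes with the stem Map, which mixes kinases and microtubule-associated proteins, 12 were lower and 1 higher by edgeR (median 1.07 times lower, Fisher's exact adjusted p = 0.0234). The stems Ndufb, Ndufa and Cox, largely of the respiratory chain, also passed as higher, with 9 of 10, 9 of 14 and 14 of 25 (Fisher's exact adjusted p = 8.95e-07, 4.61e-05 and 8.95e-07). No other family passed.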
